A study of Mus musculus with 12 samples.

How the data were processed

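The series holds 12 RNA-seq libraries of mouse embryonic stem cells: ER-ribosome-bound RNA and whole-cell RNA, each with scramble or Lsg1 siRNA, in 3 biological replicates. Per the labels' protocols, ribosomes labelled at the ER were affinity-purified, and libraries were made by poly-A selection from 750 ng of RNA with 9 PCR cycles and sequenced as paired 150 bp reads. The raw counts per gene were deposited as HTSeq tables. Per the submitters' processing notes, reads were aligned to GRCm39 with STAR 2.7.9a and counted with HTSeq 0.11.2, and DESeq2 (no version given) was used for the submitters' own comparisons. In every library the counts assigned to genes lie above the number of read pairs that the labels give as the target, and whether more pairs were sequenced or read ends were counted singly is not known here. The strand setting and the annotation release are not given in the sources used here.

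Each table lists 55416 Ensembl gene IDs and 5 summary lines, which were kept out of library sizes and tests. Of all lines' reads, 2.65% to 5.26% fell in no feature, 6.09% to 8.23% aligned to several places and 0.970% to 1.16% were ambiguous. Gene names, biotypes, GC content and the length of the longest transcript came from a GENCODE release on the older GRCm38 assembly, matched by gene ID without version; 52083 IDs (94.0%), with 99.5% of the reads, had a name. Genes without a match are given by ID.

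Counts were scaled by TMM and filtered with filterByExpr, which left 17702 genes. They were tested with edgeR 4.0.16 (quasi-likelihood F-test, 8 residual degrees of freedom, biological coefficient of variation 4.42%, prior count 2) in R 4.3.3, with 1 mean per group and all 12 libraries in the fit. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The comparisons were Lsg1 against scramble siRNA in each fraction, ER-bound against whole-cell RNA for each siRNA, and the interaction. Log2 folds are given with their SE, and CPM as mean ± SD of 3 replicates. The SD holds both counting error and differences between cultures, and no separate counting interval was computed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

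The 27 gene lists covered ribosome assembly (late 60S maturation, nucleolar factors), cytosolic and mitochondrial ribosomal proteins, nuclear and mitochondrial respiratory chain genes, proteins made at the ER (secretory, chaperone, translocon, solute carrier and Tmem lists), Slc25 carriers, cytosolic proteins, proteasome, Zfp genes, nuclear noncoding RNAs, stress and signalling (Atf4, p53, cholesterol synthesis, interferon, immediate early and heat-shock genes), mitosis, and cell states (naive, primed, primitive endoderm, 2-cell-like, fibroblast or feeder). They were tested with camera (limma 3.58.1, inter-gene correlation preset to 0.01, adjusted over the lists within a comparison). Ribosomal protein and 2-cell-like genes share reads with copies or pseudogenes.

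Named genes were Lsg1, the 8 largest rises and falls among genes past the threshold with a mean of at least 5 CPM in the higher group, the same direction in all 3 same-numbered pairs and a given name, and up to 3 members of each list with the smallest p; 1 gene that this rule selects is not reported here. All genes named as risen, fallen, higher or lower went the same way in all 3 pairs unless the text says otherwise. Lists, comparisons, tests, this rule and the alternatives were fixed before the data were examined, apart from leaving out 2 libraries together, which was chosen after seeing the data.

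The alternatives were DESeq2 size factors, library totals, no filter on low counts, a stricter filter (2 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a replicate block, removal of mitochondrial and ribosomal protein genes, an offset for trends with GC content and length (splines with 5 degrees of freedom), and each library left out in turn. List tests were also run with an estimated correlation and with fry, and not with the GC and length offset. Deviations of same-numbered ER-bound libraries from their group means correlated in all 3 pairs (0.392, 0.147 and 0.333), so the number was taken as a pairing there; for comparisons between fractions the pairing comes from the shared lysates.

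The tests were checked on counts simulated from each gene's mean and spread in the deposited tables, with 200 genes changed. The changed genes were drawn from those with a mean of at least 1 CPM, so the shares found do not cover tested genes below that level. Apart from that change, each gene had 1 mean over all libraries, without differences between fractions, pairing or libraries that stand apart. Of changes of 2-fold, 100% were found for both siRNA comparisons, and 95.5% for the interaction; of changes of 1.5-fold, 92.5% were found in whole-cell RNA, 95.5% in ER-bound RNA and 80.6% for the interaction. Of the smallest simulated changes, with a median log2 size of 0.31 in whole-cell RNA, 0.31 in ER-bound RNA and 0.30 for the interaction, 76.1%, 68.7% and 43.3% were found. Unchanged genes made up 8 of 187, 8 of 184 and 7 of 153 calls. Adjusted p-values depend on how many genes change, so these shares need not hold where few do. Lsg1 itself, with a log2 fold of -0.55 in whole-cell RNA, did not pass there (edgeR adjusted p = 0.245).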

Results

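RNA was sequenced from mouse embryonic stem cells of the E14Tg2a.4 line in which the large-subunit ribosomal protein Rpl31 carries a tag that can be biotinylated. ALIBi, a proximity-labelling system, was targeted to the endoplasmic reticulum (ER), and the ribosomes it biotinylated were affinity-purified, so that the mRNAs bound to them could be sequenced. Whole-cell RNA came from the lysates that went into the purifications. The cells had received either a scramble control siRNA or an siRNA against Lsg1, a GTPase that acts in the cytoplasmic maturation of the 60S ribosomal subunit. The 12 libraries form 4 groups of 3, labelled biological replicate 1 to 3 in each: ER-ribosome-bound RNA with scramble siRNA, whole-cell RNA with scramble siRNA, ER-ribosome-bound RNA with Lsg1 siRNA and whole-cell RNA with Lsg1 siRNA. Each library held between 38092178 and 56522114 reads assigned to genes. The first principal component, with 68.5% of the variance, separated all 6 ER-bound libraries from all 6 whole-cell libraries. In 2 libraries, ER-bound scramble replicate 3 and whole-cell Lsg1 replicate 3, the unnamed gene ENSMUSG00000119584.1 reached 18590 and 14890 CPM (counts scaled to library size), against 1158 to 3991 CPM in the other 10. The counts of genes called in each comparison were also taken without these 2 libraries.

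Lsg1 (ENSMUSG00000022538.21), the siRNA's target, was lower in both fractions of the cells that received its siRNA. In whole-cell RNA it stood at 98.0 ± 15.1 CPM (SD, n = 3) against 143 ± 6.38 CPM with scramble siRNA, 68.5% of the control level. On ER-labelled ribosomes it stood at 43.5 ± 8.62 CPM against 148 ± 4.46 CPM, 29.4% of the control level. In each fraction, every library with Lsg1 siRNA lay below every library with scramble siRNA. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the fall on ER-labelled ribosomes passed, with a log2 fold of -1.77 (SE 0.11, adjusted p = 6.3e-08). The same test over all genes did not pass Lsg1 in whole-cell RNA, where the log2 fold was -0.55 (SE 0.10, edgeR adjusted p = 0.245). Without the 2 libraries named above, the whole-cell value was -0.67, with an edgeR adjusted p of 0.0127. Between settings that adjusted p ran from 1.7e-33 without a low-count filter to 1.00 without whole-cell scramble replicate 2.

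**Figure D1:**
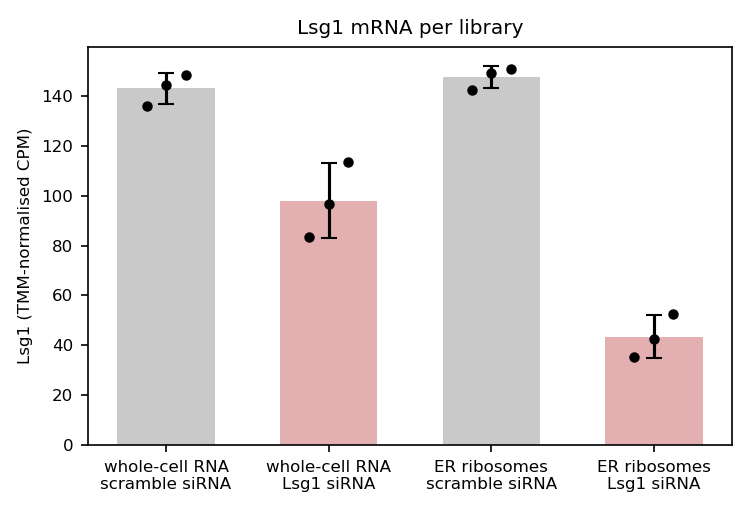
Lsg1 mRNA in each library, in TMM-normalised CPM. Bars give the mean of 3 replicates, error bars the SD and points the single libraries; the 3 ER-bound Lsg1 siRNA libraries lie lowest, with a mean of 43.5 against 148 for the ER-bound scramble libraries.

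Which mRNAs the ER-labelled ribosomes carried was read from ER-bound against whole-cell RNA in the scramble cells. None of the 12 libraries held RNA of all ribosomes, so a difference can reflect overall translation as well as location at the ER. The ER-labelled ribosomes carried more of the mRNAs that are translated at the ER and almost none of those made inside mitochondria. Chaperones and unfolded protein response genes of the ER were higher for 27 of 30 members and lower for 3, with a median log2 fold of 0.69. Pdia3, a disulfide isomerase of the ER lumen, stood at 816 ± 34.8 CPM on ER-labelled ribosomes against 385 ± 8.81 CPM in whole-cell RNA (SD, n = 3). Mitochondrially encoded mRNAs, which mitochondrial ribosomes translate, were lower for all 13 members. Mitochondrial ribosomes lack Rpl31, so purification by its tag would lower these mRNAs wherever ribosomes were labelled. Their fall therefore does not bear on labelling at the ER. The cytochrome b mRNA mt-Cytb stood at 26.6 ± 3.75 CPM against 3664 ± 127 CPM. Over the 7 mitochondrial mRNAs with at least 1000 whole-cell reads, the ER-bound level was between 0.725% and 1.62% of the whole-cell level across both siRNAs. With the 3 mRNAs that had no ER-bound read set to a floor of 3 reads per group, the list median was -6.54 in scramble cells and -6.08 in Lsg1 siRNA cells.

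Genes for secreted, matrix and cell-surface proteins were higher for 55 of 79 members and lower for 11, with 13 not passing. Progranulin (Grn, log2 fold 1.47), the tetraspanin Cd81 (1.36) and the lysosomal membrane protein Lamp1 (1.04) were among the higher ones. Lefty2, a secreted Nodal antagonist, reached a log2 fold of 1.70 (SE 0.05), and Serpine2, a secreted protease inhibitor, 2.15 (SE 0.06), the largest rise that the rule for named genes selected. The carboxypeptidase Cpz reached 2.03 at only 5.54 CPM, the epoxide hydrolase Ephx1 1.82 and the proteoglycan Sdc4 1.57. The targeting and translocon list was higher for 42 of 53 members and lower for 4; its members Ddost, of the oligosaccharyltransferase, and Ssr2, of the translocon-associated complex, had log2 folds of 1.12 and 1.00. Genes named only as transmembrane (Tmem) proteins were higher for 160 of 203 and lower for 4, Tmem19 with a log2 fold of 1.24. Solute carriers outside the Slc25 family were higher for 160 of 235 and lower for 7. Slc25 carriers of the mitochondrial inner membrane were higher for 15 of 44 and lower for 9. Cholesterol synthesis genes were higher for 20 of 31 and lower for 8, and Ebp, a sterol isomerase, had a log2 fold of 1.06.

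Members of lists whose products are mostly made in the cytosol differed too, as did p53 targets, which mix both kinds, but none of the lists in this paragraph passed as a whole with an estimated correlation (adjusted p of 0.053 to 0.60). Of 32 p53 target genes, 24 were higher and 4 lower; Perp, a desmosomal membrane protein, had a log2 fold of 1.73 (SE 0.05). The 2-cell-like list was higher for 13 of 16 members and lower for none, with a median log2 fold of 1.07; its Zscan4 members are nuclear proteins encoded by near-identical copies, so their single values are uncertain. Nuclear-encoded respiratory chain subunits were higher for 62 of 77 and lower for 6, Cox4i1 with a log2 fold of 0.91. Cytosolic ribosomal proteins were higher for 66 of 85 and lower for 8, and mitochondrial ribosomal proteins for 50 of 78 and lower for 4. Immediate early and heat-shock genes were higher for 12 of 17 and lower for 1. Once a trend with GC content and transcript length was removed, the median of cytosolic ribosomal proteins turned from 0.20 to -0.03, and those of the respiratory chain (0.25), mitochondrial ribosomal proteins (0.13) and immediate early genes (0.34) came to 0.060, 0.0010 and 0.088.

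The lists in this paragraph had more members lower than higher, and none of them passed as a whole with an estimated correlation (adjusted p of 0.065 to 0.57). Zinc finger (Zfp) genes were lower for 205 of 371 and higher for 31, and genes of G2 and mitosis lower for 14 of 24 and higher for 2. The mitotic motor Cenpe had a log2 fold of -1.81 and the topoisomerase Top2a one of -0.87. Late 60S maturation factors were lower for 11 of 18 and higher for 3, with the nucleolar GTPase Gnl2 at -0.63 and the exportin Xpo1 at -0.64. The GTPase Gtpbp4 of the same list stood at -0.57, and at 0.03 with the GC and length trend removed. Nucleolar biogenesis factors were lower for 32 of 43 and higher for 6, abundant cytosolic enzymes and cytoskeleton lower for 35 of 62 and higher for 12, and nuclear noncoding RNAs lower for 12 of 29 and higher for 6. With the same trend removed, the medians of late 60S factors (-0.35), Zfp genes (-0.21) and the cytosolic list (-0.080) came to -0.20, -0.12 and -0.26, and with library totals alone those of the cytosolic list, noncoding RNAs (-0.12) and nucleolar factors (-0.21) to -0.0019, -0.045 and -0.13. Eif3a, a translation initiation factor subunit, had a log2 fold of -0.71. Lsg1 itself differed between the fractions by 0.04 (SE 0.10, edgeR adjusted p = 0.733), a value whose sign turned in some settings.

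By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 10422 of 17702 tested genes differed between the fractions in scramble cells, 5279 higher on ER-labelled ribosomes and 5143 lower, and 692 and 568 of them by at least 2-fold. Scaling by library totals alone moved the median of all genes to 0.11 and the split to 6438 higher and 4144 lower. With camera at a preset correlation, 19 of the 27 lists passed. With an estimated correlation 4 of these held: mitochondrially encoded mRNAs (adjusted p = 0.0036), the secretory list (0.044), the ER chaperones (0.044) and the Tmem genes (0.022). For the other 15, the adjusted p with an estimated correlation was 0.053 for the translocon list and for the immediate early genes, 0.065 for G2 and mitosis, 0.081 for solute carriers, 0.081 for p53 targets, 0.19 for Zfp genes, 0.32 for late 60S factors, 0.38 for the 2-cell-like list, 0.38 for cholesterol synthesis, 0.41 for the respiratory chain, 0.52 for nucleolar factors, 0.57 for the cytosolic list, 0.57 for mitochondrial ribosomal proteins, 0.57 for noncoding RNAs and 0.60 for cytosolic ribosomal proteins. Without ER-bound scramble replicate 1 the noncoding RNAs no longer passed (camera, limma, adjusted p = 0.078). Adjusted over the list alone, counts were 56 higher for the secretory list, 162 for Tmem genes, 161 for solute carriers and 67 for cytosolic ribosomal proteins, 7 for nucleolar factors and 36 lower for the cytosolic list, and the same as over all genes for the others.

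Of the 8 lists whose camera test did not pass, naive pluripotency genes were higher for 18 of 30 and lower for 11, among them Tdgf1, a Nodal co-receptor, at 0.99 and the DNA dioxygenase Tet2 at -1.07. The Atf4 stress-response list was higher for 11 of 35 and lower for 17, the proteasome higher for 19 of 43 and lower for 11, and the interferon list higher for 4 of 17 and lower for 5. Primed and early lineage markers were higher for 3 of 18 and lower for 5, primitive endoderm markers higher for 4 of 17 and lower for 3, and fibroblast or feeder markers higher for 7 of 15 and lower for 2. The proteasome's median was positive and its mean negative, and the interferon list's median negative and its mean positive. With the GC and length trend removed the proteasome's median turned negative, and with library totals alone or a stricter low-count filter the median of the primed markers turned positive.

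**Figure D2:**
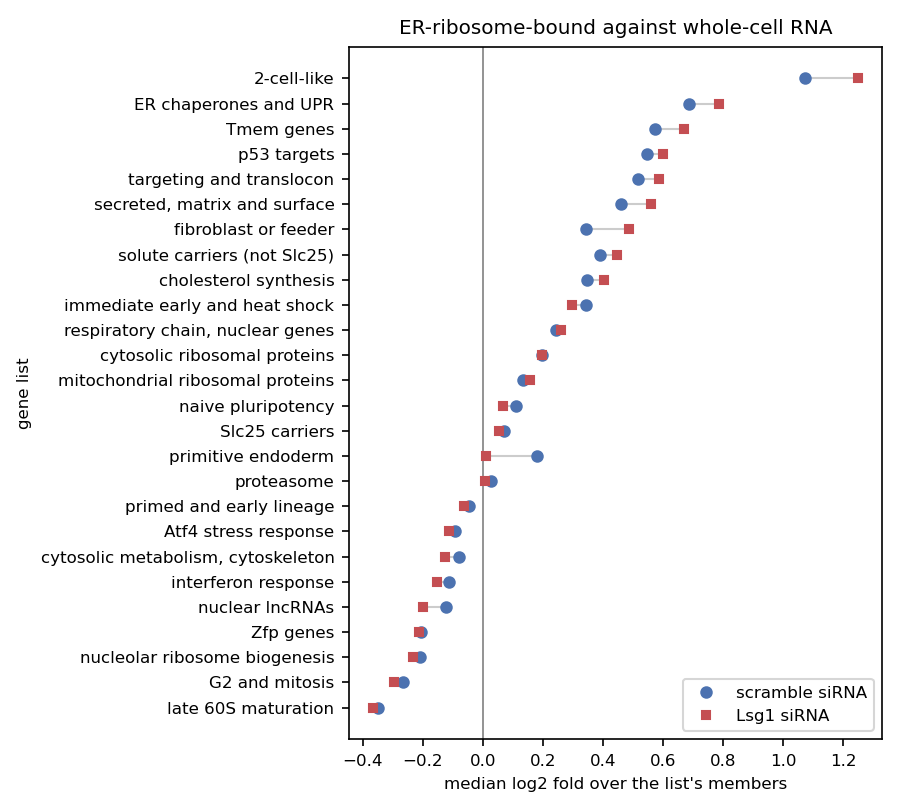
Median log2 fold of ER-ribosome-bound against whole-cell RNA for 26 gene lists, with scramble siRNA (circles) and Lsg1 siRNA (squares); mitochondrially encoded mRNAs, at -6.90 and -6.66 as fitted, lie outside the axis and are left out. The 2-cell-like list and the ER chaperones lie highest and the late 60S maturation factors lowest. The medians of cytosolic ribosomal proteins and of the proteasome turn negative with a GC and length correction for both siRNAs. Those of mitochondrial ribosomal proteins, Slc25 carriers and pluripotency genes do so with Lsg1 siRNA alone. That of primed markers turns positive with library totals and with a stricter low-count filter for both siRNAs. With Lsg1 siRNA it also turns positive without ER-bound Lsg1 replicate 1. The near-0 medians of the proteasome and, with Lsg1 siRNA, of primitive endoderm markers also turn with other settings.

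The same question was asked of the cells that received Lsg1 siRNA, and the ER-labelled ribosomes again carried more ER-translated mRNAs. ER chaperones were higher for 27 of 30 members and lower for 3, with a median log2 fold of 0.79, and Pdia3 stood at 886 ± 14.1 CPM against 385 ± 3.68 CPM (SD, n = 3). The targeting and translocon list was higher for 45 of 53 and lower for 4 (median 0.59), the secretory list higher for 57 of 79 and lower for 8 (0.56), and the Tmem genes higher for 167 of 203 and lower for 4 (0.67). Solute carriers were higher for 176 of 235 and lower for 6. Grn, Cd81 and Lamp1 had log2 folds of 1.49, 1.43 and 1.15, and Serpine2 one of 2.17. All 13 mitochondrially encoded mRNAs were lower, mt-Cytb at 28.6 ± 2.90 CPM against 3755 ± 51.8 CPM. Lsg1 was lower on ER-labelled ribosomes than in whole-cell RNA of these cells, with a log2 fold of -1.18 (SE 0.11, edgeR adjusted p = 2.6e-08).

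The p53 targets were higher for 25 of 32 members and lower for 4 after Lsg1 siRNA, Perp with a log2 fold of 1.86 and the antiproliferative gene Btg2 with 1.34. The 2-cell-like list was higher for 13 of 16 and lower for none, the respiratory chain higher for 62 of 77 and lower for 6, and cholesterol synthesis higher for 22 of 31 and lower for 7. Fibroblast or feeder markers were higher for 11 of 15 and lower for 2. The cytosolic list was lower for 41 of 62 and higher for 8, Zfp genes lower for 206 of 371 and higher for 29, and G2 and mitosis genes lower for 14 of 24 and higher for 3. Noncoding RNAs were lower for 16 of 29 and higher for 4. With the GC and length trend removed, the respiratory chain median came from 0.26 to 0.053, that of Zfp genes from -0.21 to -0.14 and that of the cytosolic list from -0.13 to -0.31. Library totals alone brought the cytosolic list to -0.038, Zfp genes to -0.12 and noncoding RNAs from -0.20 to -0.11.

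In the Lsg1 siRNA cells, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 10683 of 17702 genes, 5412 higher and 5271 lower; library totals alone moved the median of all genes to 0.11 and the split to 6686 and 4142. With camera, 20 of the 27 lists passed at the preset correlation. The 5 that held with an estimated correlation were the mitochondrially encoded mRNAs (adjusted p = 0.0039), the Tmem genes (0.017), and, each at 0.048, the secretory, ER chaperone and translocon lists. Among the named lists that did not hold, the adjusted p with an estimated correlation was 0.061 for solute carriers, 0.068 for G2 and mitosis, 0.070 for p53 targets, 0.17 for Zfp genes, 0.31 for the 2-cell-like list, 0.31 for cholesterol synthesis, 0.37 for fibroblast markers, 0.41 for the respiratory chain, 0.49 for the cytosolic list and 0.53 for noncoding RNAs. Adjusted over the list alone, 183 solute carriers, 170 Tmem genes, 58 secretory genes, 14 2-cell-like genes and 6 noncoding RNAs were higher, 7 solute carriers and 5 Tmem genes were lower, and the other lists named for these cells kept their counts. Between the siRNAs, 4618 genes were called higher and 4685 lower in both, against 1614 and 1531 for independent lists of those sizes; these comparisons share no library. The 5 genes called in opposite directions, chosen after their values were seen, were Lage3, Csgalnact2, Bod1, Ppox and the unnamed ENSMUSG00002075795.1, the last in 2 of 3 pairs each. Only Lage3 among these 5 passed the interaction test given below. Across genes, which are not independent replicates, the log2 folds of the comparisons had a Pearson r of 0.894 and a Spearman rho of 0.869, and an r of 0.294 with no low-count filter.

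What the Lsg1 siRNA changed at the transcript level was read from whole-cell RNA. The changes were small, and p53 target genes lay above 0 most evenly. Of the 32 measured p53 targets, 29 had a positive log2 fold, with a median of 0.091. The polo-like kinase Plk2 stood at 30.9 ± 3.38 CPM against 24.5 ± 1.21 CPM (SD, n = 3), a log2 fold of 0.33 (SE 0.07, edgeR adjusted p = 0.69). Btg2 had a log2 fold of 0.31 (SE 0.05, edgeR adjusted p = 0.22), and the Akt inhibitor Phlda3 stood at 35.4 ± 1.34 CPM against 31.0 ± 0.596 CPM (log2 fold 0.19, edgeR adjusted p = 0.70). No p53 target passed over all genes, and 11 were higher adjusted over the list alone. Camera at the preset correlation put the list higher, with an adjusted p of 1.7e-20; the adjusted p was 0.14 with an estimated correlation.

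Camera also put the 2-cell-like list (median 0.16, adjusted p = 0.043) and the respiratory chain subunits (0.018, 0.043) higher, and the cholesterol synthesis genes (-0.042, 0.0065) and ER chaperones (-0.028, 0.045) lower. Each of these 4 had an adjusted p of 0.95 with an estimated correlation, and each was lost when any of 2 to 4 single whole-cell libraries was left out, with camera adjusted p-values of 0.051 to 0.85. Leaving out 1 library also brought the respiratory chain median to 0.0050, that of cholesterol synthesis to -0.016 and that of ER chaperones to -0.015. The median of the late 60S maturation factors was 0.012, that of nucleolar factors 0.0087 and that of cytosolic ribosomal proteins 0.012; camera did not pass them, with adjusted p-values of 0.79, 0.44 and 0.40. The remaining 19 lists did not pass either, and no list but the p53 targets had a member called adjusted over the list alone.

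By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 17702 genes passed in whole-cell RNA. At an unadjusted p under 0.05 there were 731 genes, and the smallest adjusted p was 0.22. DESeq2's Wald test called 5 genes and limma-voom 0. Named after their values were seen, the 5 were Btg2, Plk2, Nme4, Serpine2 and Vamp3. Without the 2 libraries that stood apart, edgeR called 4 genes: Btg2, Plk2, Serpine2 and Lsg1.

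What the Lsg1 siRNA changed among the mRNAs on ER-labelled ribosomes was read from ER-bound RNA of both siRNAs. Nme4, a nucleoside diphosphate kinase of mitochondria, rose from 53.9 ± 3.98 to 97.7 ± 2.42 CPM (SD, n = 3), a log2 fold of 0.86 (SE 0.04, edgeR adjusted p = 5.0e-09). Lage3, a subunit of a tRNA-modifying complex, rose from 30.6 ± 1.30 to 48.1 ± 1.36 CPM (log2 fold 0.65, SE 0.04). After Lsg1, the largest named falls were in Csgalnact2, a chondroitin sulfate synthesis enzyme (-0.68, SE 0.07), and Vamp3, a vesicle fusion protein of recycling endosomes, which fell from 67.0 ± 1.76 to 44.4 ± 1.26 CPM (-0.59, SE 0.04). Most other changes were small. In each gene list most members did not pass; 9 of 32 p53 targets and 15 of 203 Tmem genes rose, and 7 of 30 naive pluripotency genes fell. No list passed as a whole with an estimated correlation (lowest adjusted p = 0.066).

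Other named rises were in the cyclic nucleotide-gated channel subunit Cnga3 (log2 fold 0.64), the T cell costimulator Cd80 (0.56), the guidance receptor Robo4 (0.56), Ccdc194 (0.51), the D-glutamate cyclase Dglucy (0.51) and the ER peptide transporter Tap1 (0.50). The largest named falls went on with Prss35 (-0.57), the transcriptional repressor Prdm1 (-0.52), the microtubule-end protein Mapre2 (-0.50), Serpinb6c (-0.46) and the formin Fhod3 (-0.41), and the call of Fhod3 was lost without ER-bound Lsg1 replicate 2 (edgeR adjusted p = 0.061).

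Of the 32 p53 targets, 9 rose and none fell, or 17 adjusted over the list alone, with a median log2 fold of 0.12. Btg2 rose from 48.2 ± 2.27 to 65.8 ± 1.41 CPM (log2 fold 0.45), and Cd80 and Tap1 belong to this list too. Of 203 Tmem genes, 15 rose and none fell (28 adjusted over the list alone), including Tmem18 (0.36), Tmem43 (0.31) and Tmem127 (0.28). Of 235 solute carriers, 18 rose and 1 fell (37 and 3 adjusted over the list alone), with the heme transporter Slc48a1 at 0.32 and the mitochondrial sodium-calcium exchanger Slc8b1 at 0.27. In the targeting and translocon list 6 rose and 1 fell of 53 (16 and 1 adjusted over the list alone). Its member Srprb, one subunit of the receptor for the signal recognition particle, rose (0.23), and Srpr, the other subunit, fell (-0.19). Of 79 secretory genes, 12 rose and 2 fell (23 and 5 adjusted over the list alone): the semaphorin receptor Plxnb2 rose (0.34), the sialomucin Podxl rose (0.28), and the Nodal antagonist Lefty1 fell (-0.39).

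Of 30 naive pluripotency genes, 7 fell and 1 rose (9 and 2 adjusted over the list alone). Fbxo15 (-0.19) and the transcription regulator Prdm14 (-0.20) fell, and Spry4, an antagonist of receptor tyrosine kinase signalling, rose (0.18). Of 62 cytosolic enzymes and cytoskeleton genes, 5 fell and none rose (7 lower adjusted over the list alone). Tubulin Tuba1a fell from 128 ± 0.355 to 112 ± 0.510 CPM (-0.19), and aldolase Aldoa (-0.10) fell as well, a call lost in 5 settings (edgeR adjusted p of 0.053 to 0.105). In the Atf4 list 3 of 35 fell and 1 rose (12 and 2 adjusted over the list alone): the serine synthesis enzyme Phgdh (-0.15) and the seryl-tRNA synthetase Sars (-0.12) fell and the amino acid transporter Slc7a5 rose (0.21). The calls of Sars, Slc7a5 and Srpr were lost without ER-bound Lsg1 replicate 2, with edgeR adjusted p-values of 0.054, 0.057 and 0.051. Of 16 2-cell-like genes 3 rose and none fell (7 adjusted over the list alone), Zscan4d with a log2 fold of 0.46 among copies that share reads.

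Among genes of ribosome assembly, 1 of 18 late 60S factors fell, the co-chaperone Dnajc21 (-0.12), a call lost without ER-bound Lsg1 replicate 2 (edgeR adjusted p = 0.074). Of 43 nucleolar factors 2 rose, Nop16 (0.22) and Rrp1 (0.11), the latter lost in 10 settings (edgeR adjusted p of 0.065 to 0.339). None of 85 cytosolic and none of 78 mitochondrial ribosomal proteins passed. In the ER chaperone list 3 of 30 rose, Derl2, Derl1 and Pdia3 (0.17, 0.14 and 0.12), and each was lost in at least 7 settings (edgeR adjusted p of 0.051 to 0.342). In the respiratory chain list 3 of 77 rose and 2 fell, and in the cholesterol list 2 of 31 rose, among them the fatty acid desaturase Fads1 (0.15), a call lost in 8 settings (edgeR adjusted p of 0.056 to 0.212). One proteasome gene of 43, 1 Slc25 carrier of 44 and 1 primitive endoderm marker of 17 rose; of Zfp genes 2 rose and 2 fell of 371. In the interferon list 1 of 17 fell, Oas1a (-0.26), and in the immediate early and heat-shock list 1 of 17, Hspa1b (-0.23), lost in 2 and 7 settings (edgeR adjusted p of 0.061 to 0.175). Adjusted over the list alone, 8 respiratory chain genes rose and 2 fell, 6 ER chaperones rose and 1 fell, 4 Slc25 carriers rose and 2 fell, 3 cholesterol genes rose and 1 fell, 3 proteasome genes rose and none fell, and no Zfp gene passed. No mitochondrially encoded mRNA, noncoding RNA, primed or early lineage marker, fibroblast marker or gene of G2 and mitosis passed.

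By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 710 of 17702 genes changed on ER-labelled ribosomes, 465 higher and 245 lower. The split was more even in some settings: 364 and 364 with no low-count filter, 347 and 303 with mitochondrial and ribosomal protein genes removed, 506 and 426 with the GC and length offset, and 463 and 391 without scramble replicate 1. It was less even, 483 and 195, with library totals alone. The median absolute log2 fold of the 710 genes was 0.195, and 709 of them moved the same way in all 3 same-numbered pairs, the exception being Adam19. The replicate numbers were taken to pair the ER-bound libraries, and with the number as a block the count was 1178, 749 higher and 429 lower, with all 710 among them. Only 2 genes fell by at least 2-fold, Lsg1 and Gm44321, the latter from 0.227 CPM. The count moved by over 1.5 times without any of 4 libraries: 312 without scramble replicate 2, and 367, 290 and 432 without Lsg1 replicates 1, 2 and 3. It was 521 without the 2 libraries that stood apart.

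Camera at the preset correlation passed 9 lists on ER-labelled ribosomes. Higher were the p53 targets (adjusted p = 3.7e-13), the translocon list (5.2e-07), Tmem genes (5.2e-07), solute carriers (5.8e-07), the 2-cell-like list (1.6e-05) and the secretory list (0.0020). Lower were the cytosolic list (4.2e-05), naive pluripotency (5.1e-05) and the Atf4 list (0.0020). With an estimated correlation none passed, with an adjusted p of 0.066 for pluripotency, 0.18 for p53 targets, 0.18 for Tmem genes, 0.25 for solute carriers, 0.33 for the translocon, 2-cell-like and Atf4 lists, and 0.69 for the secretory and cytosolic lists. The secretory list was also lost without ER-bound Lsg1 replicate 1 (camera adjusted p = 0.46). Fry's directional test (limma) gave these 9 lists unadjusted p-values of 2.9e-05 for pluripotency to 0.033 for the cytosolic list.

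**Figure D3:**
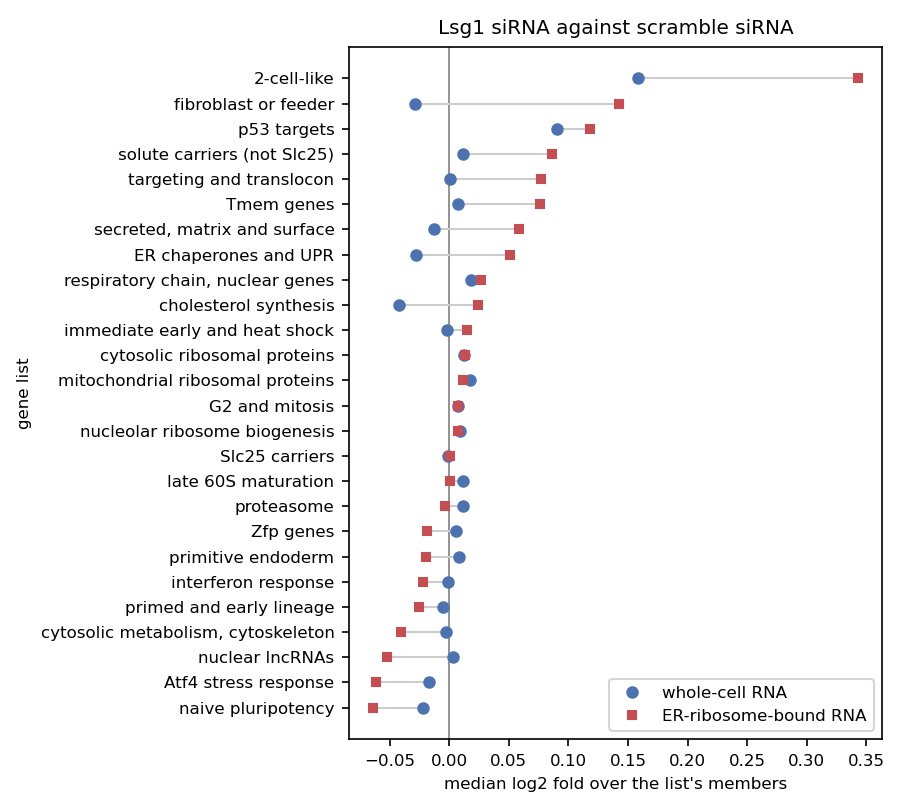
Median log2 fold of Lsg1 siRNA against scramble siRNA for 26 gene lists, in whole-cell RNA (circles) and ER-ribosome-bound RNA (squares). In ER-bound RNA the 2-cell-like median was 0.34 and the naive pluripotency median -0.064, and both kept their sign in every fit; lists with medians near 0 changed sign between fits.

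Of the 710 genes that changed on ER-labelled ribosomes, 631 had the same sign in whole-cell RNA, 402 of the higher and 229 of the lower ones, and 146 of the 710 reached an unadjusted p under 0.05 there. The lysates of the fractions are shared, so this does not compare independent cells. Their whole-cell folds were smaller: the median was 0.046 for the higher and -0.056 for the lower genes. Across all tested genes, which are not independent replicates, the log2 folds of both fractions had a Pearson r of 0.00725 and a Spearman rho of 0.191; with a stricter low-count filter r was 0.252.

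**Figure D4:**
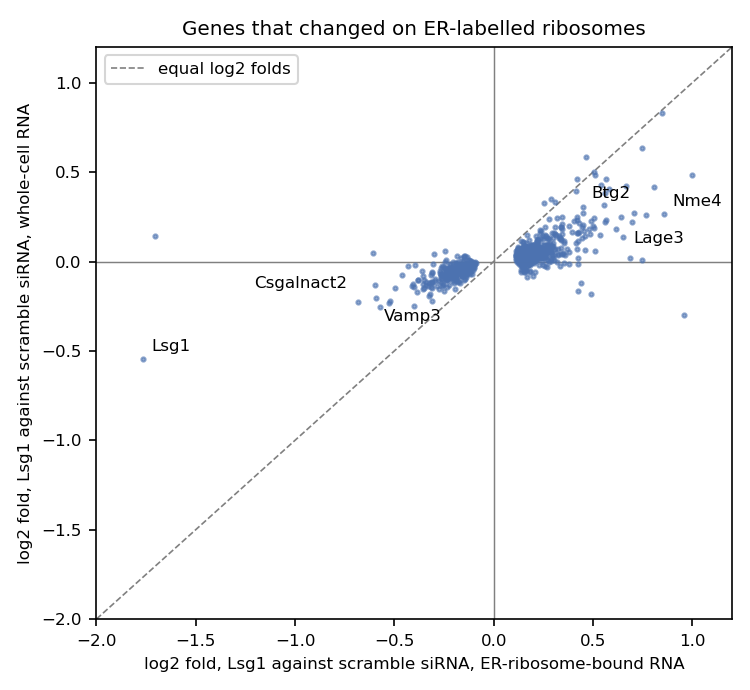
Log2 fold of Lsg1 siRNA against scramble siRNA for the 710 genes called in ER-ribosome-bound RNA, with ER-bound RNA on the x axis and whole-cell RNA on the y axis. Each point is a gene, the dashed line marks equal folds, and selecting genes by the x axis favours large values there; Lsg1 lies at -1.77 and -0.55.

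Whether the share on ER-labelled ribosomes changed beyond the transcript level was read from the interaction. It is the ER-bound minus whole-cell difference with Lsg1 siRNA minus that with scramble siRNA. Without a library of all ribosomes, a change in overall translation and one in ER association cannot be told apart here. Nme4 (ENSMUSG00000024177.10) and Lage3 (ENSMUSG00000015289.5) rose more on ER-labelled ribosomes than in whole-cell RNA, by log2 values of 0.59 (SE 0.06, edgeR adjusted p = 4.5e-04) and 0.51 (SE 0.06, 0.0013). Lsg1 and Vamp3 (ENSMUSG00000028955.4) fell more there, by log2 values of -1.22 (SE 0.15, edgeR adjusted p = 0.0013) and -0.39 (SE 0.06, 0.026). The call of Vamp3 was lost without any of 8 single libraries, with edgeR adjusted p-values of 0.060 to 0.115. Srprb (0.18), Tmem18 (0.32), Plxnb2 (0.21) and Lefty1 (-0.22) had interaction values of the sign they had on ER-labelled ribosomes, without passing (edgeR adjusted p of 0.40, 0.39, 0.43 and 0.43).

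By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, these were the 4 genes of 17702 that passed the interaction, all of them in the same direction in all 3 same-numbered differences. Paired by lysate, as the series' design states that both fractions came from the same lysates, the test called 10 genes, the 4 among them. Camera at the preset correlation passed 9 lists. Membrane and secretory proteins (secretory, ER chaperone, translocon, solute carrier and Tmem lists), cholesterol synthesis and fibroblast markers were higher, with camera adjusted p-values of 5.5e-07 for the translocon list to 0.025 for the fibroblast markers. The cytosolic list and naive pluripotency were lower (1.8e-04 and 0.012). The adjusted p was 0.43 to 0.70 with an estimated correlation, so that none passed there. Noncoding RNAs did not pass (0.056, and 0.80 with an estimated correlation), and their median of -0.053 came to 0.00042 without ER-bound scramble replicate 3. They did pass with the lysate block (0.021) and without ER-bound scramble replicate 1 (1.8e-04), ER-bound Lsg1 replicate 3 (2.7e-06) or whole-cell Lsg1 replicate 1 (0.025). Over the lists alone, 1 translocon gene and 1 ER chaperone were higher, and no member of the other 25 lists passed. The p53 targets (median 0.014, camera adjusted p = 0.49) and the 2-cell-like list (0.13, 0.070) did not pass. The p53 median turned negative in some settings, to -0.0069 without whole-cell and -0.0048 without ER-bound Lsg1 replicate 3. The 2-cell-like median came to 0.033 without ER-bound scramble replicate 1.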

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

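The tests of explanations in this part were chosen after the results were seen; the counts over other splits of the libraries were planned.

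Single genes were singled out because the effect of the Lsg1 siRNA differed between the fractions by the interaction test. The log2 differences were 0.59 for Nme4 (edgeR adjusted p = 4.5e-04), 0.51 for Lage3 (0.0013), -1.22 for Lsg1 (0.0013) and -0.39 for Vamp3 (0.026), each in the same direction in all 3 same-numbered differences.

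Lists were singled out for the same reason, by camera at the preset correlation. The median differences were 0.073 for the secretory list (62 of 79 members positive), 0.058 for ER chaperones (25 of 30), 0.073 for the translocon list (44 of 53), 0.082 for solute carriers (166 of 235), 0.062 for Tmem genes (144 of 203), 0.070 for cholesterol synthesis (24 of 31) and 0.15 for fibroblast markers (11 of 15). They were -0.041 for the cytosolic list (6 of 62 positive) and -0.042 for naive pluripotency (6 of 30). With single libraries left out these medians kept their sign, but several moved far. The furthest values were 0.045 for the secretory list, 0.044 for solute carriers, 0.032 for Tmem genes and 0.030 for cholesterol synthesis. For the cytosolic list and pluripotency they were -0.082 and -0.064. None of the 9 passed with an estimated correlation (adjusted p of 0.43 to 0.70) or with fry's directional test (limma adjusted p of 0.14 to 0.38). Cholesterol synthesis no longer passed without whole-cell scramble replicate 3 (camera, limma, adjusted p = 0.059) or ER-bound Lsg1 replicate 1 (0.098). Fibroblast markers no longer passed without whole-cell scramble replicate 1 (0.051), ER-bound scramble replicate 3 (0.15), ER-bound Lsg1 replicate 1 (0.17) or whole-cell Lsg1 replicate 2 (0.086).

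Each comparison of 3 libraries with 3 has 10 splits, which cannot give a share under 0.05. The splits did not keep same-numbered libraries paired, nor, between fractions, libraries of the same lysate. In whole-cell RNA all 10 splits called as many genes as the real one, 0 each (edgeR; 731 genes at an unadjusted p under 0.05, 5 by DESeq2, 0 by limma-voom). In ER-bound RNA the real split called 710 and the highest other 41, so that 1 split reached the real count. Between fractions the real splits called 10422 and 10683 and every other 0, again 1 split each. For the interaction 2 splits reached the real 4, the highest other also calling 4.

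Among genes called in ER-bound RNA, knockdown effects were larger there than in whole-cell RNA. With genes selected in ER-bound RNA without the replicate in which they were measured, the whole-cell effect was 0.338 of the ER-bound effect (SE 0.023, n = 3 left-out replicates), below 1 in all 3. For these genes this argues against equal effects seen through a different spread or depth alone. Selection by ER-bound RNA favours genes with larger effects there, so the ratio does not describe genes in general. Whole-cell RNA may also hold RNA of cells that were not transfected, which would give every gene the ratio of Lsg1, 0.445 (SE 0.045). The difference was -0.107 (SE 0.051), only just beyond 2 SE, with an SE from 3 overlapping gene sets that takes the ratios as independent. Both ratios come from the same left-out replicates, at 0.332, 0.381 and 0.302 for the other genes and 0.514, 0.462 and 0.360 for Lsg1. The other genes lay below Lsg1 each time, but they were selected by ER-bound RNA and Lsg1 was not. That selection alone can lower their ratio, and 3 replicates cannot decide this, so 1 common fraction stays open. A response of ER-labelled ribosomes beyond the transcript level stays open: 4 genes passed the interaction.

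Membrane and secretory lists were higher and the cytosolic list lower on ER-labelled ribosomes after knockdown by camera, but none passed with an estimated correlation (adjusted p = 0.33 for translocon, 0.18 for Tmem, 0.25 for solute carriers, 0.69 for secretory and 0.69 for cytosolic genes), nor the secretory list without ER-bound Lsg1 replicate 1 (0.46). With the GC and length offset the translocon median was 0.069 (SE 0.013), against 0.077 (SE 0.012) without it. The offset took away little of the median, which argues against such a trend as its whole cause. These SEs are over member genes, which are not independent replicates, and do not measure the spread between libraries. The median was 0.049 without ER-bound Lsg1 replicate 1, and 0.075 in 1 other split of the libraries. A difference between the siRNAs in labelling or purification, or in carry-over of lysate RNA, would scale the whole enrichment, and both stay open. Of the 465 genes that rose on ER-labelled ribosomes, 341 were called higher there than in whole-cell RNA of scramble cells and 68 lower. Of the 245 that fell, 66 were higher and 120 lower. Among all 17702 tested genes, 5279 were higher and 5143 lower. These comparisons share the ER-bound scramble libraries. Outside the lists, the knockdown fold had a mean slope against enrichment of 0.050 (SE 0.031), with -0.013, 0.080 and 0.083 for pairs 1, 2 and 3, which is within 2 SE of 0. From these slopes, translocon medians of -0.0061, 0.044 and 0.047 would follow in pairs 1, 2 and 3, against 0.082, 0.092 and 0.057 measured. Such scaling could thus hold part of the rise in pairs 2 and 3 and none in pair 1, which does not decide the question. Bounds first set on the lowest single pair and on carry-over of mitochondrial mRNAs were dropped, since 1 pair excludes nothing and mRNAs inside mitochondria need not be carried over like cytosolic ones.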

How the results depend on the processing

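Leaving out together the 2 libraries that stood apart (ER-bound scramble replicate 3 and whole-cell Lsg1 replicate 3) was chosen after seeing the data; all other alternatives were planned. Where a value changed, the cause was not tested.

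Genes called in whole-cell RNA (0) came to 26 with no low-count filter, 5 with DESeq2, 2 with only the groups compared, 1 with the GC and length offset, 8 with the offset and replicate block, 4 without both libraries, and 0 without any single library. In ER-bound RNA (710) the count was 375 with only the groups compared, 1544 with the offset and replicate block, and 290 to 854 without single libraries. The interaction (4) gave 59 with no filter, 18 with DESeq2, 20 with the offset and replicate block, and 3 to 8 without single libraries. Without single libraries, ER-bound against whole-cell RNA gave 9608 to 9941 genes with scramble and 9962 to 10318 with Lsg1 siRNA.

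With the replicate number as a block, ER-bound RNA gave 1178 genes and the interaction 13, or 10 paired by lysate. In whole-cell RNA the number paired the libraries less clearly, with correlations of 0.309, 0.0053 and 0.345, and replicate 2 not best with its own number. Between fractions, replicate 2 was as weakly paired by lysate (-0.050 with scramble and 0.016 with Lsg1 siRNA). With 3 replicates per group this check cannot settle a pairing. In whole-cell RNA the block gave 5 genes and passed mitochondrial ribosomal proteins (camera, limma, adjusted p = 0.039) and pluripotency (0.037). Without the block, these lists had camera adjusted p-values of 0.054 and 0.068 at the preset correlation. With an estimated correlation these were 0.95 and 0.62. Apart from the noncoding RNAs of the interaction, the block changed no other list call.

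Lsg1 in whole-cell RNA passed with no filter (-0.55), only the groups compared (-0.55), the replicate block (-0.55), the offset and replicate block (-0.56) and without both libraries (-0.67); without single libraries it was -0.67 to -0.45 and did not pass. In ER-bound RNA it was -1.94 to -1.64 and passed each time. Its value between fractions in scramble cells (0.045) was -0.013 with the offset, -0.012 with the offset and replicate block, and -0.012 to 0.063 without single libraries. Gtpbp4 between fractions was 0.032 with the offset and 0.031 with the offset and replicate block.

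The correlation of the knockdown folds (0.00725) was 0.252 with a stricter filter, 0.0558 without both libraries and -0.0306 to 0.101 without single libraries. That of the enrichments (0.894) was 0.294 with no filter, 0.974 with a stricter one, 0.877 without both libraries and 0.876 to 0.899 without single libraries. Of 62 list tests that passed, 9 did with an estimated correlation, and 59 to 70 passed without single libraries. With fry, 58 passed by its directional test and 78 by its mixed test, which takes changes in either direction.

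Of named genes' values under alternatives, 812 kept side and direction and 88 lost the call in ER-bound RNA, against 399 and 8 for the interaction. A gene that passed in neither fit counts as kept. Only 4 genes passed the interaction, so most of its 399 values are of genes that stayed uncalled, and all 8 losses were of Vamp3. The tallies therefore do not compare how stable the calls of the comparisons are. Between fractions 1410 with scramble (5 turned sign) and 434 with Lsg1 siRNA kept both. Simulated changes were found less often for the interaction than within a fraction, so small differences between fractions are missed more often.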

Other observations

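The tests in this part were chosen after the results were seen.

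Short mRNAs were higher on ER-labelled ribosomes than long ones. In scramble cells, protein-coding genes split into 5 equal bins by longest transcript had median log2 folds of 0.24, 0.14, 0.024, -0.082 and -0.32 from shortest to longest, and with Lsg1 siRNA of 0.23, 0.13, 0.016, -0.090 and -0.31. In the shortest bin 1611 genes were higher and 197 lower, and in the longest 465 and 1740. Cytosolic ribosomal proteins such as Rplp2 (0.47) and respiratory chain subunits such as Cox4i1 (0.91) are short mRNAs, and the mitotic genes Cenpe (-1.81) and Cenpf (-1.62) long ones.

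Lage3 was lower on ER-labelled ribosomes with scramble siRNA (-0.36) and higher with Lsg1 siRNA (0.15), and Csgalnact2 went from 0.27 to -0.19, Bod1 from -0.11 to 0.092 and Ppox from 0.16 to -0.17. Of these genes, picked for their opposite calls, only Lage3 passed the interaction test of that difference. The single calls of Bod1 (edgeR adjusted p of 0.019 and 0.042) and Ppox (0.037 and 0.021) lay near the threshold. In ER-bound scramble replicate 3 and whole-cell Lsg1 replicate 3, Lars2 stood at 2137 and 1338 CPM, against 131 to 420 in the other 10 libraries, and Mir6236 at 483 and 266 CPM against 24.9 to 91.0. Like those of ENSMUSG00000119584.1, these may be rRNA-like reads, which was not tested. The values need not be levels of the Lars2 mRNA or of a microRNA.

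Zscan4 mRNAs, which encode nuclear proteins of the 2-cell-like state, were higher on ER-labelled ribosomes in scramble cells, with a median log2 fold of 1.10 (SE 0.059) over 6 members that share reads; p53 target mRNAs of nuclear or cytosolic proteins had 0.24 (SE 0.16) over 19 members, within 2 SE of 0. With the GC and length offset the Zscan4 median was 0.93 (SE 0.051), so the offset took away little of it, which argues against such a trend as its whole cause. The p53 median was 0.26 (SE 0.14), so that the offset did not lower it, though this test could not decide for members already within 2 SE of 0. All these SEs are over member genes, which are not independent replicates, least of all the Zscan4 copies, and do not measure the spread between libraries. The labelled ribosomes may come from a part of the cells with more p53 and 2-cell-like transcripts. The pooled median of 0.46 lay at percentile 100 of 10000 random sets of other nuclear and cytosolic mRNAs matched on level and length (median -0.18). So did that of the p53 members alone (random median -0.23, 95th percentile -0.10). GC content was not matched, and most of the lists drawn on had medians below 0 in this comparison. These were late 60S (-0.35), G2 and mitosis (-0.27), nucleolar (-0.21), Zfp (-0.21) and cytosolic (-0.080). The others, proteasome and pluripotency, had 0.028 and 0.11, and all tested genes 0.030. A high percentile was thus likely from the choice of lists, and shows only that these members lay above them. Such a part of the cells and a location of these mRNAs at the ER would both give high values, so that they cannot be told apart.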
